A study of Mus musculus with 53 samples.

How the data were processed

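The data are peak lists of 53 chromatin immunoprecipitation libraries from macrophages of C57BL/6 (WT, 30 libraries) and BXH2/TyJ (BXH2, 23 libraries) mice, with antibodies against IRF8, PU.1, STAT1, STAT2, IRF1 and H3K27ac. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to genome build mm9 and peaks were called with MACS 1.4. Per the labels, each list was called against an input library. The labels give neither the peak-calling parameters nor which input served which library. Per the labels, 5 of the H3K27ac lists of the LPS series rest on pooled reads of 2 samples each, and no other pooling is stated. Each list holds 1 peak per line with chromosome, start, end and a peak score, and no header.

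The authors deposited a score per peak, which was read from its values as the -10 log10(p) of the peak caller. The lowest score of the lists is 100, so the authors' threshold was taken as a score of at least 100. Scores depend on sequencing depth, which the lists do not give, and were therefore never compared between lists. They served to rank peaks within a list and, in an alternative, to filter every list at a score of at least 200 whatever its depth. Of 853905 peaks, 72.8% had a score of at least 200. The precision of a peak number is not known without reads, and shares of sites carry 95% Wilson intervals for counting error only.

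Groups were formed from antibody, strain, stimulation series, stimulus and time, as the labels give them. Starts were converted to positions counted from 1. A single peak on the mitochondrial chromosome was left out. No pair of lists of the same antibody shared more than 0.549% of its peaks with identical start and end (355 pairs), so no list was a copy of another. The lists of interferon-β at 60 min in the IFN series and at 1 h in the IFNB series, which the labels describe alike apart from the dose, differed 1.78-fold (WT) and 2.33-fold (BXH2) in length. The longer list held 90.2% and 93.5% of the shorter one, and the shorter held 51.7% and 39.8% of the longer.

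All values were computed from the lists with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks shared a region when they overlapped by at least 1 bp. Regions were the merged union of the lists compared, and a library called a region when a peak of it overlapped the region. Regions of 1 strain were those called in every library of that strain and in no library of the other strain, over the matched conditions (3 pairs for IRF8 and PU.1, 8 stimulated pairs for STAT1, 6 pairs for H3K27ac). Peak numbers were compared on the log2 scale between libraries matched for series and condition by exact two-sided paired permutation tests that enumerate every sign flip. The p-values of the 4 antibodies were adjusted by the Benjamini-Hochberg method. The smallest possible p is 0.25 with 3 pairs and 0.0312 with 6.

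WT IRF8 sites were the merged union of the 3 WT lists. The share held by another factor was set beside the mean of 100 circular shifts of that factor's peaks along each chromosome. H3K27ac at IRF8 sites was compared between strains over 6 matched conditions, with PU.1 sites of all 3 WT times without IRF8 as the control. Regions gained or lost under stimulation had to be gained or lost in both strains. The main comparisons, their tests and most alternatives were fixed before the data were examined. Comparisons added afterwards were the STAT1 regions of a single ligand, the PU.1 peaks kept between strains with and without IRF8, and the covered length of H3K27ac. The plan also did not include the factors held by regions of a single strain or ligand and by gained or lost regions. Nor did it include the overlap of IRF8 peaks between strains by score. PU.1 peaks without IRF8 were weighted to the score deciles of the peaks with IRF8.

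Regions named in the text followed a rule set before the data were examined: up to 5 per direction with the highest mean score percentile within the lists that hold them, with mm9 coordinates. Ties, which occur in the H3K27ac lists of the IFN series, were broken by position. The gene table at hand belongs to another build, GRCm38.p6, and on chromosome 7 the lists reach position 152507700 where its furthest gene ends at 145324059. No gene was therefore assigned to a region, and the planned comparisons of gene lists and sequence motifs were not made, since no mm9 annotation or genome sequence was at hand.

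The main comparisons were recomputed with scores of at least 100 and of at least 200. Those that rest on overlap were also recomputed with an overlap of at least 50% of the shorter interval and with all lists of a comparison trimmed by score to the length of the shortest. Each matched pair was left out in turn for peak numbers and regions by strain, H3K27ac and PU.1 at IRF8 sites, the STAT1 response and the comparison of ligands. For overlap of 50%, the peaks of the first list of a group served as regions, since a merged region contains its peaks whole. Not recomputed were the covered length of H3K27ac, the overlap of IRF8 peaks between strains and the IRF8 classes kept in BXH2. Nor were the factors held by regions of 1 strain or ligand, those held by gained or lost regions, and the STAT2 and IRF1 regions called only after LPS. The counting of one-sided regions was tested on simulated data for the IRF8 strain comparison with 20000 regions. It recovered 100% of 200 WT-only and 50 BXH2-only regions, and 2.76% of regions simulated without a difference were one-sided where 2.78% were expected. The one-sided regions were simulated as called in every library of their strain and in none of the other, so full recovery checks the counting alone. Regions without a difference had equal call rates in both strains, unlike the real IRF8 lists. The simulation therefore gives no rate of false one-sided regions for these data. The score-matched PU.1 comparison recovered a mean of -19.9 points (SD 0.724 over 20 simulations of 20000 peaks) where -20 points had been simulated.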

Results

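Peak lists from chromatin immunoprecipitation and sequencing were read for 53 libraries of mouse bone marrow-derived macrophages, cells grown from bone marrow in conditioned medium and used on day 7. Of these, 30 libraries came from C57BL/6 mice, called wild type (WT) here. The other 23 came from BXH2/TyJ mice (BXH2), a recombinant inbred strain that carries a missense allele of Irf8. The antibodies recognised IRF8 (6 libraries), PU.1 (6), STAT1 (23), STAT2 (3), IRF1 (3) and histone H3 acetylated at lysine 27, H3K27ac (12). IRF8 and IRF1 are interferon regulatory factors, PU.1 is the ETS factor that occupies most macrophage enhancers, STAT1 and STAT2 carry the signal of interferon receptors to the nucleus, and H3K27ac marks active promoters and enhancers. In the LPS series, cells were left untreated or received 10 ng/ml of lipopolysaccharide (LPS) for 2 h or 4 h. IRF8, PU.1 and H3K27ac were profiled there in both strains, STAT2 and IRF1 in WT, and STAT1 in WT at 2 h. In the IFN series, STAT1 and H3K27ac were profiled in both strains without treatment and after 30 and 60 min of interferon-β, at a dose that the labels do not give. In the IFNB and IFNG series, STAT1 was profiled in both strains without treatment and after 1, 2 and 4 h of 100 U/ml of interferon-β or interferon-γ.

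The lists held 853905 peaks on the nuclear chromosomes. PU.1 lists were the longest, with 60931 to 75169 peaks, and STAT1 lists ranged from 67 to 13938. H3K27ac lists held 15424 to 25511 peaks and covered 75.0 to 129 Mb. The number of reads behind each list is unknown, because the lists carry peaks only. Each stimulated condition had 1 library, so values below have no replicate error unless one is given. The untreated condition was repeated across series for STAT1 (WT 1510 ± 2119 peaks and BXH2 596 ± 742, SD, n = 3 each) and for H3K27ac (WT 21795 ± 3842 and BXH2 22348 ± 4474, SD, n = 2 each). The untreated STAT1 lists of 1 strain therefore differed by up to 21.7-fold. Intervals given with shares are 95% Wilson intervals, which cover counting error only.

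**Figure D1:**
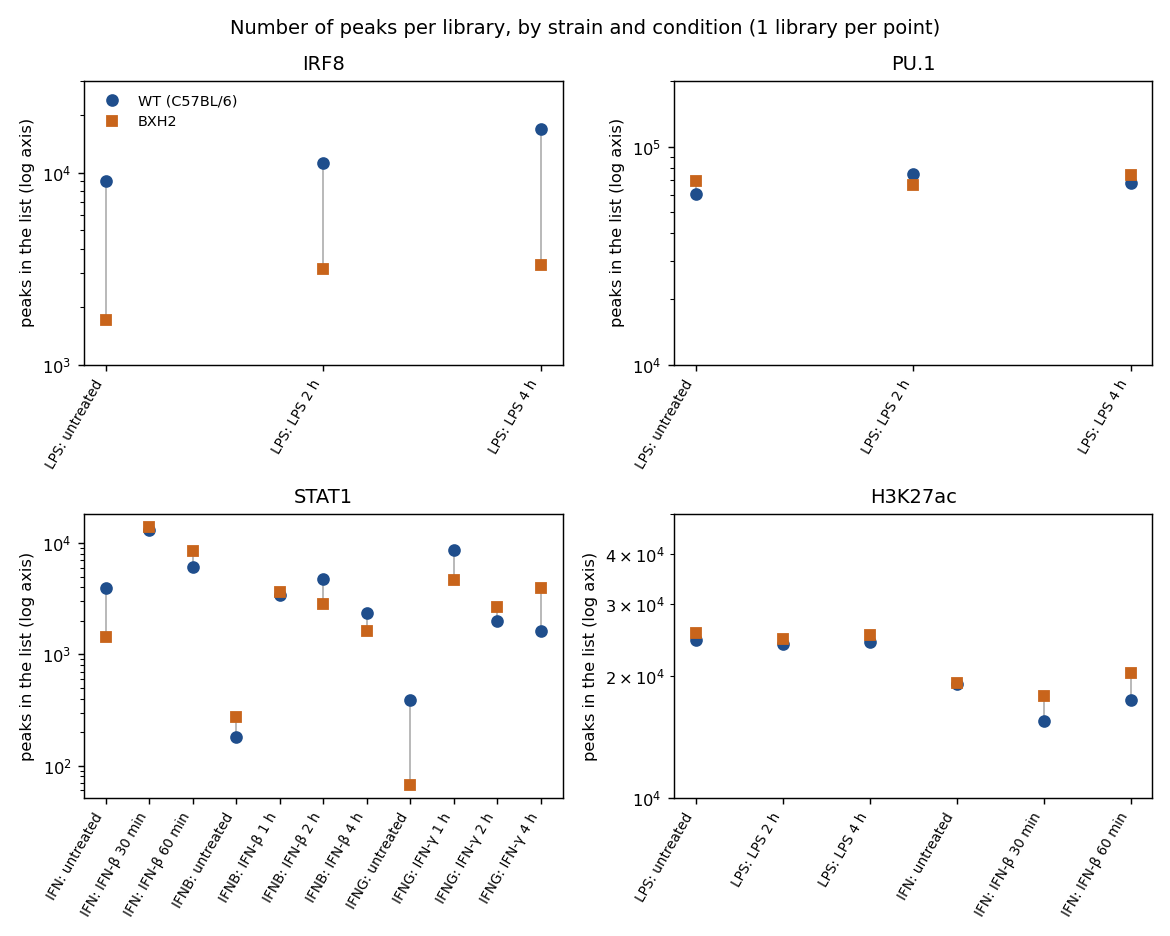
Number of peaks in each library (vertical log axis) by condition (horizontal axis) for IRF8, PU.1, STAT1 and H3K27ac, with WT as circles, BXH2 as squares and a line joining each matched pair of libraries. The 3 WT IRF8 lists hold 9056 to 16793 peaks and the 3 BXH2 lists 1710 to 3298, whereas the PU.1 and H3K27ac lists of the strains lie close together.

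The first comparison asked how IRF8 occupancy differs between WT and BXH2 macrophages. WT cells had 9056 IRF8 peaks untreated, 11251 after 2 h of LPS and 16793 after 4 h, and BXH2 cells had 1710, 3152 and 3298. The WT lists were on average 4.58-fold longer (log2 2.20 ± 0.31, SD, 3 pairs), and WT was higher in 3 of 3 pairs. Of 19542 merged IRF8 regions, 3574 were called in every WT library and in no BXH2 library, 3 were called in every BXH2 and no WT library, and 1144 were called in every library. The BXH2 peaks were largely a subset of the WT peaks: 96.0% of them untreated, 89.8% at 2 h and 97.8% at 4 h overlapped a WT IRF8 peak, whereas 18.1%, 25.3% and 19.2% of WT peaks overlapped a BXH2 peak. The share kept followed peak score, with 77.3% of the highest score decile of the untreated WT list also called in BXH2 and 1.21% of the lowest.

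The WT-only IRF8 regions with the highest scores lay on chromosome 2 at 145959557 to 145960952, 6179481 to 6181099 and 16104440 to 16105560, on chromosome 10 at 104927431 to 104928695 and on chromosome 9 at 89928486 to 89929702 (build mm9). Each held a PU.1 peak in untreated WT cells, and those at 145959557 and 16104440 on chromosome 2 and on chromosome 9 held none in untreated BXH2 cells. Of all 3574 WT-only regions, 98.2% held a PU.1 peak of WT and 72.6% one of BXH2 at some time of the LPS series. H3K27ac peaks lay at 4 of the 5 named regions in untreated WT cells and at 0 of them in untreated BXH2 cells. The 3 BXH2-only regions, on chromosome 9 at 76088991 to 76089650 and on chromosome 1 at 90198031 to 90201336 and 90135032 to 90138626, held neither PU.1 nor H3K27ac in either untreated list. Among the regions called in every library, 64.2% also held an IRF1 peak and 76.0% an H3K27ac peak of untreated WT cells, against 35.6% and 48.5% of the 3574 WT-only regions, of which 42.1% held an H3K27ac peak of untreated BXH2 cells. These shares were not matched on score or length (medians of 1337.5 and 986 bp). At matched score, WT IRF8 peaks with IRF1 were kept in BXH2 more often by 9.67 points untreated, 5.24 at 2 h and 4.20 at 4 h.

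The difference in IRF8 peak number gave p = 0.25 in the exact two-sided paired permutation test, the smallest value that 3 pairs allow, and p = 0.5 after Benjamini-Hochberg adjustment over the 4 antibodies compared. With every IRF8 list trimmed to the length of the shortest, 128 regions were WT only and 99 were BXH2 only. The large excess of WT-only regions thus depended on the difference in list length, which trimming removes. With full lists the counts were 6230 and 17 without the untreated pair, and 13 regions were BXH2 only without the 4 h pair.

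PU.1 occupancy was nearly the same in number in the strains. WT lists held 60931, 75169 and 67926 PU.1 peaks and BXH2 lists 69447, 66599 and 74473 (log2 WT over BXH2 -0.05 ± 0.20, SD, 3 pairs). Of 96109 merged PU.1 regions, 42923 were called in every library, 1971 in every WT and no BXH2 library, and 1493 in every BXH2 and no WT library. These groups differed in IRF8: 63.0% of WT-only PU.1 regions held a WT IRF8 peak (60.9 to 65.1%), against 24.7% of the regions called everywhere and 0.201% of the BXH2-only regions. The last share was bound to be low. BXH2-only regions lack WT PU.1 by definition, and 93.0%, 88.2% and 86.5% of WT IRF8 peaks at the 3 times held it. WT IRF1 peaks lay at 14.2% of WT-only regions, 15.8% of those called everywhere and 1.00% of BXH2-only regions. Among the 5 WT-only regions with the highest scores, those on chromosome X at 19798329 to 19799799, chromosome 3 at 139608719 to 139611058, chromosome 15 at 75568056 to 75569296 and chromosome 1 at 196601359 to 196602743 held an IRF8 peak at all 3 WT times. The remaining region, on chromosome 10 at 7970598 to 7972155, held none. The 5 BXH2-only regions with the highest scores, led by chromosome 3 at 32268560 to 32269513 and chromosome 11 at 88034975 to 88036188, held no IRF8 peak in either strain. The difference in PU.1 peak number stayed far from the threshold (exact two-sided paired permutation test, p = 0.75 where 0.25 is the smallest possible). Without the untreated pair the difference turned to log2 0.02 and the counts rose to 4941 WT-only and 3187 BXH2-only regions. BXH2-only regions numbered 4870 without the 2 h pair, and the counts were 3033 and 2438 without the 4 h pair.

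PU.1 peaks that coincided with IRF8 in WT cells were called less often in BXH2 than other PU.1 peaks of similar score. Of WT PU.1 peaks with a WT IRF8 peak of the same condition, 79.2% untreated, 79.7% at 2 h and 81.2% at 4 h were also PU.1 peaks in BXH2. PU.1 peaks without IRF8 were kept at 91.1%, 78.9% and 88.0%, so that at 2 h the deficit appeared only after weighting for score. Weighted to the same score deciles, they were kept at 97.9%, 94.8% and 96.6%, which left differences of -18.7, -15.1 and -15.4 percentage points. The gap was wide at low and middle scores: in decile 5 of the untreated list 39.6% of peaks with IRF8 were kept, against 95.9% of peaks without it. In the reverse direction, BXH2 PU.1 peaks with a WT IRF8 peak were called in WT at 99.7%, 99.8% and 99.1%, against 92.1%, 96.5% and 90.5% of score-matched peaks without IRF8. These high shares were largely set by the choice of sites, since 93.0%, 88.2% and 86.5% of WT IRF8 peaks held WT PU.1. Over the 3 times the weighted difference averaged -16.4 ± 2.03 points (SD, lower with IRF8 in 3 of 3 pairs), with p = 0.25 in the exact two-sided paired permutation test, the smallest value that 3 pairs allow. The comparison, its weighting and this test were added after the lists had been seen.

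**Figure D2:**
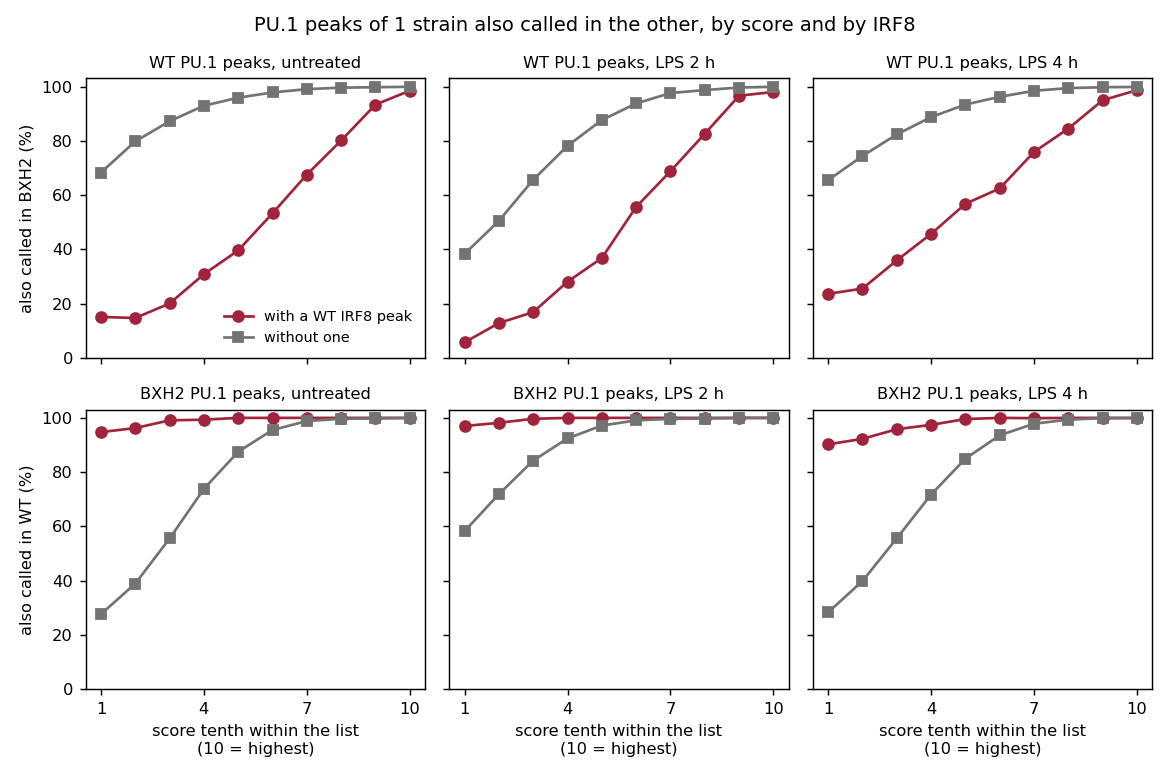
Share of the PU.1 peaks of 1 strain that were also PU.1 peaks in the other strain (vertical axis, percent) by score decile within the list (horizontal axis), with circles for peaks that overlapped a WT IRF8 peak and squares for peaks that did not. In WT lists (top) the peaks with IRF8 lie below those without it, as at 39.6% against 95.9% in decile 5 of the untreated list, and in BXH2 lists (bottom) they lie at or above them.

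IRF8 occupancy was then followed over LPS treatment, and WT IRF8 sites were divided by the times at which they were called. Of 19382 merged WT IRF8 sites, 6430 (33.2%) were called at all 3 times and are termed constitutive here, 10357 (53.4%) were called only after LPS, and 1236 (6.38%) only in untreated cells. The LPS-only sites comprised 3310 called at both 2 h and 4 h, 975 at 2 h alone and 6072 at 4 h alone. In BXH2 cells, 44.4% of constitutive sites kept an IRF8 peak at some time (43.2 to 45.6%), against 13.7% of LPS-only sites and 2.35% of the sites called only untreated. The classes were not matched on score, with which the share kept rose, and constitutive sites were called in WT at more times. The constitutive sites with the highest scores lay on chromosome 13 at 55123553 to 55124709, chromosome 10 at 93584354 to 93585989, chromosome 14 at 103876407 to 103877893, chromosome 7 at 135191837 to 135193230 and chromosome 6 at 127203619 to 127204953, and each held PU.1 in untreated cells of both strains. The LPS-induced sites with the highest scores at both 2 h and 4 h lay on chromosome 3 at 106937002 to 106938110, chromosome 2 at 58102188 to 58103394, chromosome 14 at 28188953 to 28189960, chromosome 10 at 18787646 to 18789048 and chromosome 13 at 54910124 to 54911248. None of these 5 held PU.1 in untreated WT cells, all 5 held IRF1 and STAT1 at 2 h, and all 5 kept an IRF8 peak in BXH2 at 2 h and 4 h. With 1 library per time there was no test, and list length mattered: with lists trimmed to equal length, 4941 sites were LPS only and 2418 were called only untreated, and with scores of at least 200, 4061 were constitutive and 6028 LPS only.

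Constitutive and LPS-induced IRF8 sites differed in the factors beside them. PU.1 at 4 h of LPS held 97.2% of constitutive sites (96.7 to 97.5%) and 78.1% of the LPS-only sites called at 4 h (77.3 to 79.0%). PU.1 itself was present at 49.2% of LPS-only sites before treatment and at 73.7% and 76.1% after 2 h and 4 h, whereas constitutive sites held it at 93.9%, 96.8% and 97.2%. IRF1 rose from 11.9% of LPS-only sites untreated to 45.2% at 2 h and 46.3% at 4 h, and from 22.5% to 43.1% and 42.4% of constitutive sites. STAT2, at 0.338% of LPS-only and 1.93% of constitutive sites untreated, reached 17.4% and 23.0% at 2 h. Sites without PU.1 but with IRF1 at 4 h were 10.7% (without STAT2) and 1.36% (with STAT2) of the 9382 LPS-only sites called at 4 h, against 1.62% and 0.404% of constitutive sites. H3K27ac in WT cells rose from 32.8% of LPS-only sites to 56.9% at 2 h and 60.8% at 4 h, stayed at 58.7%, 59.0% and 59.2% of constitutive sites, and fell from 46.0% to 24.8% and 23.9% of the sites called only untreated.

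**Figure D3:**
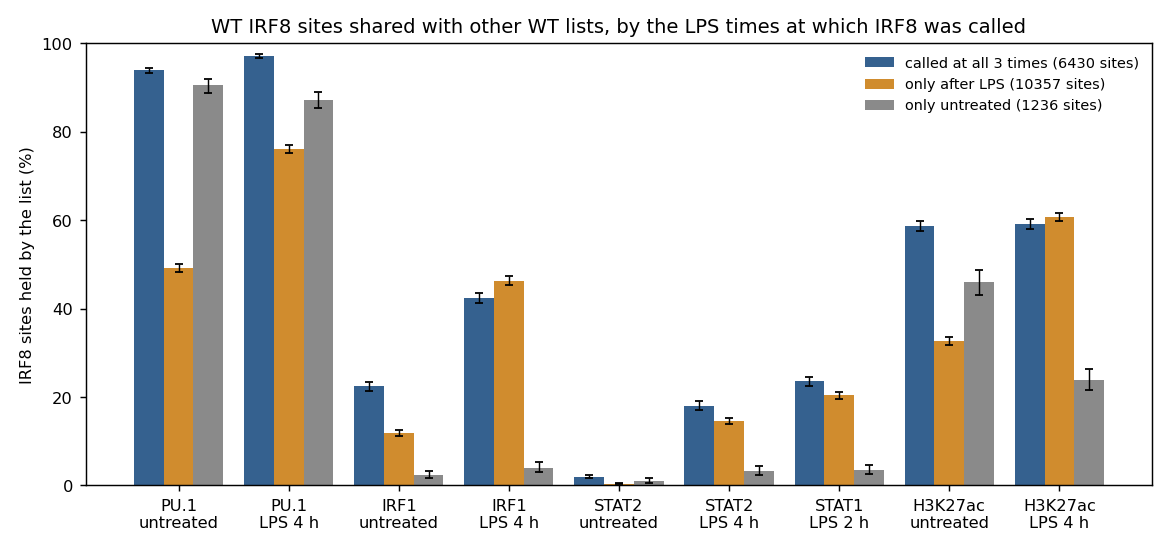
Share of WT IRF8 sites held by a peak of each list (vertical axis, percent), for 6430 constitutive sites, 10357 sites called only after LPS and 1236 called only untreated, with 95% Wilson intervals as error bars. LPS-only sites rise from 11.9% to 46.3% for IRF1 and from 32.8% to 60.8% for H3K27ac, and start at 49.2% for PU.1 where constitutive sites start at 93.9%.

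Over all WT IRF8 peaks of the same time, PU.1 was present at 93.0% untreated, 88.2% at 2 h and 86.5% at 4 h, against 4.49%, 5.97% and 5.13% when the PU.1 peaks were shifted along the chromosomes. IRF1 was present at 17.0%, 51.4% and 43.0% of IRF8 peaks and STAT2 at 1.62%, 23.2% and 16.1%, all above the highest share of 100 shifts. STAT1 at 2 h was present at 24.6%. Constitutive minus LPS-only differences at 4 h were 19.0 points for PU.1, -3.42 for IRF1 and 2.70 for STAT2, and -4.35 points for STAT1 at 2 h. The STAT2 difference turned to -5.13 points with lists of equal length and was 0.690 at scores of at least 200, the IRF1 difference moved to -7.85 and -10.01, and the PU.1 difference to 32.4 points at equal length.

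H3K27ac was compared between strains at the IRF8 sites. Constitutive IRF8 sites were acetylated more often in WT, at 58.6% on average against 53.4% in BXH2 (5.24 ± 3.20 points, SD, higher in 6 of 6 matched conditions). LPS-only sites showed no such excess on average over the 6 conditions, at 44.7% in WT and 45.9% in BXH2 (-1.24 ± 3.52 points, SD, 6 pairs). That mean includes untreated and interferon-β conditions. WT was higher in 2 of 6 pairs, those at 2 h and 4 h of LPS (1.43 and 2.79 points), where these sites were called. In the LPS series they were acetylated at 32.8% in WT and 40.2% in BXH2 before treatment, and at 60.8% and 58.0% after 4 h. At 35968 PU.1 sites without IRF8, acetylation was lower in WT in 6 of 6 conditions (-6.04 ± 2.61 points, SD). In the LPS series the difference at these PU.1 sites was -8.98 points untreated, -6.73 at 2 h and -7.93 at 4 h. Relative to those sites, acetylation in WT exceeded that in BXH2 by 7.26 ± 1.42 points at all IRF8 sites, 11.3 ± 1.69 at constitutive sites and 4.80 ± 3.98 at LPS-only sites (SD, 6 pairs, positive in 6 of 6).

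Exact two-sided paired permutation tests gave p = 0.0312 for each of these 3 relative differences, the smallest value that 6 pairs allow, and p = 0.0312 after Benjamini-Hochberg adjustment over the 3 site classes. The direct strain difference gave exact p = 0.0312 at constitutive sites, 0.188 at all IRF8 sites and 0.531 at LPS-only sites. With control sites matched on PU.1 score, a choice made after seeing the data, the relative difference at LPS-only sites was 3.49 points with exact p = 0.0625. The sites were taken from WT lists only.

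Across the whole genome, H3K27ac lists were slightly longer in BXH2 in 6 of 6 conditions, by 1.07-fold on average (log2 WT over BXH2 -0.10 ± 0.09, SD), and covered 1.25-fold more sequence, with a range of 1.07 to 1.60. The lowest value came from untreated cells of the IFN series (121 Mb in WT, 129 in BXH2) and the highest from those of the LPS series (75.0 and 120 Mb). In the LPS series 5 of the lists rest on pooled reads, so the pairs were not all alike in pooling, and read depth is unknown. Of 34721 merged H3K27ac regions, 38 were called in every WT and no BXH2 library, 58 in every BXH2 and no WT library and 7596 in every library. Of the 38 WT-only regions, 36 held a WT IRF8 peak (94.7%, 82.7 to 98.5%), against 7 of the 58 BXH2-only regions (12.1%, 5.97 to 22.9%) and 49.9% of the regions acetylated everywhere. Other WT lists were skewed the same way between the strains. IRF1 lay in 57.9% of WT-only, 5.17% of BXH2-only and 46.6% of everywhere acetylated regions, and STAT2 in 28.9%, 1.72% and 28.5%. All 38 held PU.1 in WT at some time of the LPS series and 20 did in BXH2. The WT-only regions with the highest scores lay on chromosome 14 at 58925364 to 58944145, chromosome 2 at 16101183 to 16109196, chromosome 5 at 152011055 to 152016365, chromosome 18 at 46430292 to 46436721 and chromosome 3 at 38320069 to 38325254. The first 4 held IRF8 at all 3 WT times and at no BXH2 time, and the region on chromosome 2 contained the WT-only IRF8 region at 16104440. The BXH2-only regions with the highest scores, on chromosome 9 at 120731982 to 120742819, chromosome 1 at 64121832 to 64129433 and 72240966 to 72247073, chromosome 16 at 65243464 to 65251198 and chromosome 19 at 24688509 to 24692679, held no IRF8 peak.

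The difference in H3K27ac peak number gave p = 0.0312 in the exact two-sided paired permutation test, the smallest possible with 6 pairs, and failed the correction over 4 antibodies at p = 0.125 (higher in BXH2 in 6 of 6 pairs). The covered length gave the same exact p of 0.0312. Both tests rest on conditions of 2 series, which do not repeat the strain independently, so they do not measure variation between mice. With lists trimmed to equal length, 38 regions were WT only and 27 BXH2 only, the WT-only count rose to 61 without the 4 h LPS pair, and the BXH2-only count rose to 125 without the pair at 30 min of interferon-β, 105 and 100 without the LPS pairs at 2 h and 4 h, and 97 without the untreated IFN pair. Counting regions called in at least 4 more libraries of 1 strain, a choice made after seeing the data, gave 345 for WT and 977 for BXH2.

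H3K27ac also changed under stimulation in both strains together. LPS brought acetylation to 3491 regions at 2 h and 3654 at 4 h that neither untreated library held, and removed it from 3634 and 3342. After interferon-β, 1570 regions were gained at 30 min and 2455 at 60 min, and 3416 and 2275 were lost. The 30 min lists were shorter than the untreated ones in both strains, with 15424 against 19078 peaks in WT and 17792 against 19184 in BXH2. A shorter list adds losses by itself, so these counts do not separate removal from weaker libraries. With lists trimmed to equal length, the counts at 30 min were 1877 gained and 2339 lost. Of the regions gained with interferon-β, 12.6% and 9.61% already held H3K27ac in the untreated WT list of the LPS series, and 21.7% and 17.8% in that of BXH2. Gained and lost regions differed in the factors recorded under LPS. A STAT2 peak lay in 29.1% and 32.7% of regions gained at 2 h and 4 h of LPS and in 37.4% and 36.7% of those gained at 30 and 60 min of interferon-β, against 0.248%, 0.209%, 0.820% and 0.440% of lost regions. IRF1 lay in 52.2%, 52.6%, 38.5% and 42.5% of gained and 7.43%, 7.03%, 10.3% and 8.40% of lost regions, and IRF8 in 46.6%, 47.1%, 39.8% and 39.8% of gained and 19.6%, 17.2%, 18.7% and 19.2% of lost regions. PU.1 was frequent in both, with 81.6% of regions gained and 86.2% of regions lost at 2 h of LPS. Regions acetylated in every library held STAT2 at 28.5%, IRF1 at 46.6% and IRF8 at 49.9%. They were longer, with a median of 8555 bp against 3634 bp for regions gained at 2 h of LPS. Gained regions were thus closer to these than to lost regions. At 2 h of LPS 95.6% of STAT2 peaks held H3K27ac, so regions without it could hold few of them.

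Regions gained at 4 h of LPS were led by chromosome 17 at 80893962 to 80907092, chromosome 18 at 68985814 to 68996165, chromosome 3 at 152425720 to 152431429, chromosome 11 at 119020094 to 119027770 and chromosome 13 at 113390908 to 113394364, all 5 of which held STAT2 and IRF1 at 2 h. Regions lost at both LPS times were led by chromosome 2 at 5721122 to 5727538, which held IRF8 and PU.1 in both strains, and included chromosome 3 at 21717674 to 21727709, which held PU.1 and no IRF8. Regions gained at 60 min of interferon-β were led by chromosome 5 at 93446679 to 93452248, which held STAT1 and STAT2 at 2 h of LPS and no PU.1 in untreated cells. Gains in a single strain were also frequent, with 2269 in WT and 2406 in BXH2 at 2 h of LPS, and 189 regions changed in opposite directions. The untreated libraries are shared between the times of a series, so the counts at both times are not independent, and with 1 library per strain and time no test was made.

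**Figure D4:**
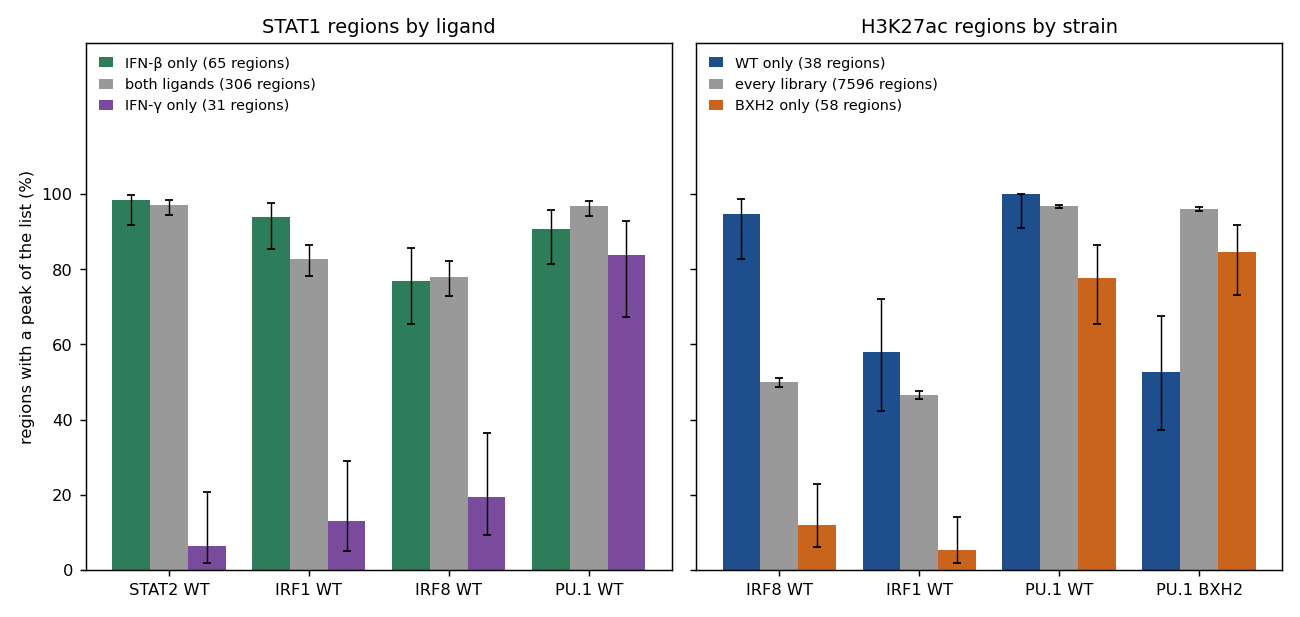
Share of regions that hold a peak of each list (vertical axis, percent, with 95% Wilson intervals), for STAT1 regions called with interferon-β only, with both ligands or with interferon-γ only (left), and for H3K27ac regions of WT only, every library or BXH2 only (right). STAT2 marks 98.5% of interferon-β-only and 6.45% of interferon-γ-only STAT1 regions, and IRF8 marks 94.7% of WT-only and 12.1% of BXH2-only H3K27ac regions.

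STAT1 occupancy rose sharply within 1 h of interferon. Peak numbers after 60 min or 1 h were on average 12.4-fold those of the untreated library of the same series (log2 3.63 ± 1.87, SD, 6 pairs), and higher in 6 of 6 pairs. With interferon-γ they went from 393 to 8720 in WT and from 67 to 4705 in BXH2, and with interferon-β in the IFNB series from 182 to 3447 and from 276 to 3656. The IFN series started from longer untreated lists, with 3954 and 1444 peaks, and rose 1.55-fold in WT and 5.91-fold in BXH2. The exact two-sided paired permutation test gave p = 0.0312, the smallest that 6 pairs allow. Without the IFN series the mean was log2 4.64 and the 4 pairs could not go below exact p = 0.125. Of the 67 untreated BXH2 peaks in the IFNG series, 32.8% lay on chromosome Y.

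STAT1 peak number showed no common direction between strains. Over 11 matched conditions the WT lists were 1.23-fold longer (log2 0.29 ± 1.08, SD), longer in 5 pairs and shorter in 6, with exact two-sided paired permutation p = 0.407. The mean ran from log2 0.0678 without the untreated IFNG pair to 0.453 without the 4 h interferon-γ pair, and was 0.179 at scores of at least 200. Of 18983 merged STAT1 regions of the stimulated libraries, 302 were called in every library, 1 in every WT and no BXH2 library and 0 the other way. The WT-only region, on chromosome 15 at 39877444 to 39879910, held PU.1 and H3K27ac in untreated WT cells and neither in untreated BXH2 cells, held a BXH2 PU.1 peak at some time of the LPS series, and held STAT2, IRF1 and STAT1 at 2 h of LPS in WT. It was not called at scores of at least 200, and the WT-only count was 3 without the 4 h interferon-γ pair and 2 without the pair at 30 min or 4 h of interferon-β or 2 h of interferon-γ.

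STAT1 regions were partly different in the interferon-β and interferon-γ series, which used an equal dose in units. At 1 h STAT1 peaks were more numerous with interferon-γ in both strains (2.53-fold in WT and 1.29-fold in BXH2), and at 2 h more numerous with interferon-β (2.37-fold and 1.05-fold). At 4 h the strains went in opposite directions, with 2344 interferon-β and 1619 interferon-γ peaks in WT against 1625 and 3973 in BXH2. Of 12282 merged regions, 306 were called in all 12 libraries, 65 in all 6 interferon-β and no interferon-γ libraries, and 31 in all 6 interferon-γ and no interferon-β libraries. STAT2 peaks of LPS-treated WT cells marked 64 of the 65 interferon-β-only regions (98.5%, 91.8 to 99.7%), 97.1% of the shared regions and 2 of the 31 interferon-γ-only regions (6.45%, 1.79 to 20.7%). IRF1 marked 93.8%, 82.7% and 12.9% of these groups and IRF8 76.9%, 77.8% and 19.4%. PU.1 was present at 90.8%, 96.7% and 83.9%, and H3K27ac of untreated WT cells at 63.1%, 74.2% and 83.9%.

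The interferon-β-only regions with the highest scores lay on chromosome 14 at 75404295 to 75412400, chromosome 3 at 65120927 to 65125423, chromosome 19 at 11129627 to 11131436, chromosome 5 at 90698749 to 90702401 and chromosome 6 at 86496258 to 86500381, and all 5 held STAT2 and STAT1 at 2 h of LPS. The interferon-γ-only regions with the highest scores lay on chromosome 11 at 69221318 to 69226161, chromosome 5 at 139852577 to 139860998, chromosome 9 at 35112307 to 35113903, chromosome 17 at 26851568 to 26855863 and chromosome 7 at 148660179 to 148664088. None of these 5 held STAT2 or IRF1 at 2 h of LPS, and 4 held H3K27ac in untreated cells of both strains. Regions shared by all 12 libraries were led by chromosome Y at 2778937 to 2797667 and 2847214 to 2873870, followed by chromosome 1 at 52167135 to 52179078, chromosome 11 at 53571248 to 53580758 and chromosome 3 at 142155158 to 142164683. Both regions on chromosome Y held PU.1 and no H3K27ac in untreated cells of both strains. Untreated STAT1 lists themselves held 13 to 43 peaks on chromosome Y. Regions called without treatment were not removed from the shared regions, so these need not be induced by interferon.

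The difference in peak number between ligands had no common direction (log2 interferon-β over interferon-γ -0.19 ± 1.02, SD, 6 pairs, 3 positive, exact two-sided paired permutation p = 0.719), and the mean turned to 0.05 at scores of at least 200, 0.04 without WT at 1 h and 0.03 without BXH2 at 4 h. The regions of a single ligand were counted after the lists had been seen, and ligand coincided with series. Their numbers were 41 and 8 at scores of at least 200, 158 for interferon-β without the WT 1 h pair and 100 without the BXH2 1 h pair, and 75 and 98 for interferon-γ without the WT 2 h and WT 4 h pairs.

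STAT2 and IRF1 occupancy in WT cells depended on LPS. STAT2 went from 282 peaks untreated to 4846 at 2 h and 3833 at 4 h, and 95.3% of its 5411 regions were called only after LPS. IRF1 went from 3596 to 14220 and 13550 peaks, and 78.0% of its 16250 regions were called only after LPS. Of STAT2 peaks at 2 h, 70.2% held STAT1 (68.9 to 71.5%), 72.3% IRF1, 51.8% IRF8, 90.4% PU.1 and 95.6% H3K27ac, where shifted lists gave 0.829%, 1.86%, 1.17%, 8.11% and 4.86%. The STAT2 regions with the highest scores called only after LPS lay on chromosome 13 at 5775154 to 5779730, chromosome 1 at 175967994 to 175972364, chromosome 10 at 18781627 to 18790631 and chromosome 6 at 146622750 to 146624749 and 66865917 to 66868149, all with IRF8, IRF1 and STAT1 at 2 h. The region on chromosome 10 contained the LPS-induced IRF8 site at 18787646. The IRF1 regions with the highest scores were led by chromosome X at 155949356 to 155951123, with IRF8 and without STAT2, and chromosome 10 at 122627888 to 122631021, with STAT2 and without IRF8. With 1 library per time there was no test, and with each pair of lists trimmed to equal length the shares of STAT2 peaks fell to 40.8% for IRF1 and 26.6% for IRF8.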

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

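The score matching of PU.1 peaks, the blocks of strain variants and the splits of the STAT1 regions by ligand were tests chosen after their result was seen, and those at IRF1 peaks without IRF8 and in 20 Mb windows were chosen after the patterns but before their own values were seen. Some results stood out because groups moved in opposite directions, and these differences were not tested. PU.1 peak number rose at 2 h of LPS in WT (log2 0.30) and fell in BXH2 (-0.06), a difference of 0.36. H3K27ac peak number fell at 60 min of interferon-β in WT (-0.13) and rose in BXH2 (0.08), a difference of -0.21. The ratio of interferon-β to interferon-γ STAT1 peaks at 4 h was log2 0.53 in WT and -1.29 in BXH2, a difference of 1.82. The same ratio averaged over strains was log2 -0.85 at 1 h and 0.66 at 2 h, a difference of -1.51. A signal outside the comparisons was 1 peak on the mitochondrial chromosome in the WT STAT1 list at 4 h of interferon-γ. No group held 4 or more libraries, so no library could be tested for lying far from the others of its group.

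IRF8 was called at far fewer regions in BXH2, with 3577 regions of a single strain in the real grouping of the 6 libraries and at most 397 in another grouping (1 of 10 splits reached the real number, and 10 splits are too few to reach a share under 0.05). The tables argue against strain variants at the sites as the whole cause: BXH strains derive in part from C57BL/6, the reference strain, yet in 0 of 126 windows of 20 Mb were under 10% of the regions called at all 3 WT times without a BXH2 peak (36.4 to 75.0% were). The ratio of that share between 5 Mb windows with few and many strain-differing PU.1 regions was 0.990. That ratio decides nothing alone, because the 5 Mb windows were not shown to follow blocks of variants. Weaker signal in the BXH2 libraries at every site alike cannot be told apart from a selective loss, because WT peaks with IRF1 were kept more often than score-matched peaks without it by 9.67, 5.24 and 4.20 points, between the bounds set for either outcome. With PU.1 in place of IRF1 the differences were 7.44 and 0.650 points at 2 h and 4 h, and -9.26 untreated over the 9 score deciles that held enough peaks without PU.1. A lower affinity or amount of the mutant protein, which the design offers as the biological explanation, was not tested apart from it.

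PU.1 peaks at WT IRF8 sites were kept in BXH2 15.1 to 18.7 points less often than other PU.1 peaks of equal score, which argues against weaker PU.1 peaks at those sites (-15.1 points at the time nearest to 0). Strain variants at the sites as the whole cause are argued against by windows of 20 Mb, of which at most 1.49% showed a deficit under 5 points at any time. The deficit in 5 Mb windows with few strain-differing PU.1 regions was at least 0.994 of that in windows with many. That ratio decides nothing alone, because the 5 Mb windows were not shown to follow blocks of variants. Choosing the sites by any list from WT cells remains open: WT PU.1 peaks with IRF1 and no IRF8 showed differences of -2.14, -9.05 and -5.69 points, at most 0.582 of that at IRF8 sites (-15.6 at 2 h against the same control peaks, which held IRF8 in neither strain). Against that control the deficit was -22.9, -20.5 and -18.9 points where BXH2 had lost IRF8 and -1.87, -2.68 and -3.42 where it kept IRF8, a gap of at least 15.4 points. The small deficit where IRF8 was kept was largely set by the choice of sites, since 98.2% of the IRF8 regions called in every library held BXH2 PU.1 at some time. The gap alone thus cannot decide whether IRF8 supports PU.1. Such support may account for part of the pattern, but a site closed in BXH2 for another reason could lose both factors, and the lists do not separate these.

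PU.1 regions of a single strain away from any IRF8 peak numbered 2214 (729 in WT and 1485 in BXH2) beside 32217 shared ones. Over all PU.1 regions the real grouping gave 3464 one-sided regions and the highest other grouping 1556, and that grouping put the untreated WT library with the untreated and 2 h BXH2 libraries (1 of 10 splits, too few for a share under 0.05). Inherited blocks of strain variants could place such regions side by side, and 13.8% of them were followed by another, against a mean of 6.62% and a highest value of 8.13% in 1000 shuffles. H3K27ac regions away from IRF8 differed by strain (at least 4 more libraries of 1 strain) at 4.27% in the windows where PU.1 differed most and at 3.16% in those where it differed least, a ratio of 1.35 that falls between the bounds set for and against blocks. Clustering of regulatory regions that share a change in trans, which was not tested, stays open as well.

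The other counts of one-sided regions were set against splits that swap the labels within matched pairs. For H3K27ac by strain, 1 of 32 splits, the real one, reached 96 regions, and the highest other gave 1. For STAT1 by ligand 1 of 32 splits reached 96, and the highest other gave 8. Under such swaps chance can be excluded at a share of 0.05 for these counts, if the pairs are taken as independent. The 6 H3K27ac pairs come from 2 series, and ligand coincides with series for STAT1, so a difference between the IFNB and IFNG series cannot be told apart from one between ligands. The STAT1 count by strain was a single region, with 0 as the highest of the other splits (1 of 100 drawn reached it). It was 0 at scores of at least 200, so it is too small to exclude chance.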

How the results depend on the processing

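The alternatives chosen after the data had been seen were scores of at least 200, control sites matched on PU.1 score, windows with few strain-differing PU.1 regions, the counts with at least 4 more libraries or at least 5 of 6 libraries, the omission of the IFN series or chromosome Y, and all settings of the PU.1 comparison at IRF8 sites and the STAT1 regions by ligand. Of 284 recomputed values, 195 kept their direction and size or side of the threshold, 52 moved, 32 lost the threshold and 5 reversed. A score of at least 100 removed no peak, so its 41 values say nothing about stability. An overlap of 50% moved only the BXH2-only IRF8 count, to 1. Lists of equal length gave 128 WT-only and 99 BXH2-only IRF8 regions, where full lists gave 3574 and 3. For PU.1 they gave 2061 and 1204. Trimming removes the difference in list length itself, so the IRF8 counts cannot tell a loss of sites from a shorter list. Lists of equal length also gave 27 BXH2-only H3K27ac regions, and 4941 LPS-only and 2418 untreated-only IRF8 sites. They gave constitutive minus LPS-only differences of 32.4 points for PU.1, -7.85 for IRF1 and -5.13 for STAT2, a reversal. They put STAT1, IRF1 and IRF8 at 64.5%, 40.8% and 26.6% of STAT2 peaks, and the PU.1 deficit at -20.3 points untreated and -16.6 at 4 h. Shorter lists hold fewer overlaps by construction, but the cause of the STAT2 reversal was not tested. Scores of at least 200 gave 953 BXH2-only PU.1 regions, 0 WT-only STAT1 regions, 4061 constitutive and 6028 LPS-only IRF8 sites, differences of -10.01 points for IRF1 and 0.690 for STAT2, a reversed log2 ligand mean of 0.0459, 41 interferon-β-only and 8 interferon-γ-only STAT1 regions, 63.3%, 67.9% and 41.3% of STAT2 peaks with STAT1, IRF1 and IRF8, and PU.1 deficits of -23.5, -17.9 and -17.6 points. Leave-one-out over 6 pairs cannot go below exact p = 0.0625, so each such test lost the threshold by construction with its direction kept: the log2 H3K27ac peak number ran from -0.116 to -0.0739, the relative acetylation from 6.83 to 7.62 points at all IRF8 sites, 10.8 to 11.7 at constitutive and 3.62 to 5.72 at LPS-only sites, and the log2 STAT1 response from 3.13 to 4.23. Without the IFN series that response was 4.64 with exact p = 0.125, and without chromosome Y it was 3.78 with exact p = 0.0312. Control sites matched on PU.1 score left 3.49 points at LPS-only sites with exact p = 0.0625; the cause was not tested. Leaving out a pair moved the PU.1 peak number from log2 -0.161 to 0.0209, a reversal without the untreated pair, and the ligand mean from -0.477 to 0.0405, with reversals to 0.0405 without WT at 1 h and 0.0307 without BXH2 at 4 h; the cause was not tested. Counts of regions held by every library grow when a pair is left out: IRF8 WT only ran from 4336 to 6230 (without the untreated pair) and BXH2 only from 3 to 17, PU.1 WT only from 2542 to 4941 and BXH2 only from 2438 to 4870, STAT1 WT only from 1 to 3, H3K27ac WT only from 44 to 61 and BXH2 only from 67 to 125, interferon-β only from 71 to 158 and interferon-γ only from 31 to 98. At least 4 more libraries gave 345 WT and 977 BXH2 H3K27ac regions, and at least 5 of 6 against at most 1 of 6 libraries gave 301 interferon-β and 250 interferon-γ regions. Leaving out an untreated library moved the mean STAT1 peak number from 288 to 2174 in WT and from 172 to 860 in BXH2, within the spread of the 3. The planned motif and gene list alternatives were not run. Read depth, which sets how many peaks a list can hold, is unknown and limits every comparison of peak numbers.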

Other observations

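No hypothesis was tested in this part, and its values were chosen for reporting after they had been seen. The share of STAT1 peaks that the strains had in common varied with stimulus and time. At 30 min of interferon-β, 81.9% of WT STAT1 peaks were called in BXH2 and 76.2% of BXH2 peaks in WT. With interferon-γ at 1 h, 49.7% of WT peaks lay in the BXH2 list and 89.4% of BXH2 peaks in the WT list, with the WT list 1.85-fold longer. At 4 h of interferon-γ, where the BXH2 list was the longer one, 74.3% of WT peaks lay in the BXH2 list and 30.9% of BXH2 peaks in the WT list. Between ligands in WT, 80.8%, 29.7% and 24.7% of interferon-β peaks lay in the interferon-γ list at 1, 2 and 4 h, while that list shortened from 8720 to 2003 and 1619 peaks. In the reverse direction the shares were 32.4%, 71.5% and 35.7%. In BXH2, 66.7%, 44.1% and 51.4% of interferon-β peaks lay in the interferon-γ list.

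IRF8 sites called only in untreated WT cells formed a small group of 1236 with few partners of the interferon pathway. At 4 h of LPS, 3.96% held IRF1 and 3.16% STAT2, while 87.3% held PU.1. The highest-scoring of them lay on chromosome 4 at 115495660 to 115496843 and chromosome 2 at 160101398 to 160102606, both with PU.1 and H3K27ac in untreated cells of both strains. Acetylation at these 1236 sites went from 46.0% to 23.9% in WT and from 44.3% to 29.0% in BXH2 over 4 h of LPS, and 1.46% of them held IRF8 in untreated BXH2 cells.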
